A study of Schizosaccharomyces pombe with 3 samples.

How the data were processed

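Labels describe 3 two-colour arrays of Tup12-GFP chromatin from Schizosaccharomyces pombe, each listed with input DNA as Cy3 and immunoprecipitated DNA as Cy5, an assignment that the protocol text gives as the general one. Per the labels' protocols, cells grew to mid-log phase in rich YES medium, chromatin was crosslinked and sonicated, and both kinds of DNA went through a 2-step amplification before labelling. No array is listed with the dyes swapped. The labels call the experiments separate, so the arrays were treated as 3 replicates of a single group. Where they are not separate cultures, p-values of single features and of sign-flip tests measure only the spread between arrays. Per the labels' protocols, slides were read with a ScanExpress scanner and quantified with TIGR Spotfinder; versions, and the genome build behind the array, are not given in the sources used here.

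The authors deposited spot intensities per channel for 22176 spots on each array, not normalized between channels. The values had already been reduced by local background: the 1st percentile of accepted spots was 1.02 to 1.17 times the SD of the background, except in the immunoprecipitate channel of replicate 2 (0.457 times), spots flagged X were listed at 0, and 14.5% to 32.3% of accepted immunoprecipitate spots lay below their own listed background. The deposited spot files also hold a fraction of unsaturated pixels, quality values and a per-spot score that is not a tail probability; these were not used in tests. The authors' series matrix holds log10 values, per the labels normalized in GeneSpring to the 50th percentile; set against the spot files they followed the log10 of the immunoprecipitate channel after a further background subtraction (r = 0.95, 0.93 and 0.94), divided by a constant per block for most spots of replicates 1 and 3 (96.8% on each within 0.03 log10 units) but for 46.3% on replicate 2, with medians of 0.02, 0.05 and 0.03. They are values of a single channel rather than ratios, with 25.2%, 37.6% and 30.9% of spots at a floor, and the cause of the block constants, and what else was done to replicate 2, stay unknown. They were used as an alternative.

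Main values were log2 of integrated Cy5 over integrated Cy3 intensity for spots accepted in both channels, centred on each array's median (0.52, -0.29 and 0.24 before centring), with repeat spots averaged. A feature was tested if it had a value on all 3 arrays, a requirement chosen after the files were seen; 1610 features had a value on 2 arrays, 1389 on 1 and 1507 on none. Control, foreign and unnamed spots, and 16 features named only as intergenic or intronic pieces without a gene, were left out. Negative control spots were accepted in 42.1%, 49.6% and 45.3% of cases in the immunoprecipitate channel but in 1.85%, 1.79% and 1.54% of cases in the input channel, so dim immunoprecipitate values hold unspecific signal. The number of arrays limits the precision.

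Feature names were matched to genes of the ASM294v3 reference annotation by systematic name, symbol or older symbol, and 9426 of 9966 features matched (94.6%); ambiguous names were left unmatched. The reference was used for names, neighbours, base composition and distances, and no base coordinates are given because no source names the build of the array. The base composition of an intergenic feature was taken from the 500 bp upstream of the start codon, since the amplified stretch itself is not given in the sources used here.

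Enrichment was tested per feature with limma (lmFit and eBayes, mean against 0, Benjamini-Hochberg adjustment over all features). The binding list followed the procedure in the labels: percentile ranks of spots within each array, the median rank over the 6 spots of a feature, and a limit at the 85th percentile. Spots without a ratio were not ranked, so a median could rest on fewer than 6 spots. Group differences were medians per array, with an exact sign-flip test over arrays, and Fisher's exact test for shares in the list. Fisher's tests treat features as independent. Gene lists, fixed before the data were examined, were iron uptake, glycolysis, glucose-repressed, core stress, transporters, histones, phosphate, zinc and copper, mating and meiosis, nitrogen starvation, corepressor and regulators, ribosomal proteins, wtf, cell-surface adhesins, Tf2 retrotransposons, translation factors and intergenic features holding tRNA genes. Features named for long intergenic regions were kept out of lists and of the features compared with them, and were included in an alternative chosen after the values were seen. A list's shift is the median of its features' means over arrays minus that of other features, and its SD is over the shifts of single arrays; for upstream histones (0.82, 0.74 and 0.80) and ribosomal proteins the single arrays all lay below the shift of means. Lists were tested with camera in limma with a preset correlation of 0.01, and repeated with an estimated correlation and with fry. With the preset, camera p-values rest on the spread across features and not on the number of arrays. No list kept its call with an estimated correlation, a form that takes its degrees of freedom from the 3 arrays and not from features. The estimate lay below the preset for glycolysis (-0.097), glucose-repressed (-0.0096), core stress (-0.020) and tRNA regions (-0.025). It lay above the preset for iron uptake (0.42) and transporters (0.024). The lost calls can therefore not be put down to correlation within lists alone. By contrast, fry, which compares with the array median and not with other features, called all 14. The comparison of regions with and without gene starts had been planned; because intergenic features were taken to lie upstream of the gene that names them, from the correlation of neighbouring features and not from stated positions, divergent and tandem regions were compared in its place.

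Named features followed a rule fixed before the data were examined: the 12 intergenic and 8 ORF features with the highest mean among those enriched and above 0 on all arrays, the 5 lowest by the mirrored rule, up to the 3 highest and the 1 lowest member of each list, and in any case the features of tup12, tup11, ssn6, fbp1, fio1, str1, cta3 and ste11. Among the features given beyond that rule, chosen after their values were seen, are frp1, pap1 and the upstream feature of ght3. Alternatives covered normalization, background, flags, input signal, left-out replicates, the series matrix, repeat spots, thresholds, centring, ranking, base composition, distance and list settings. The normexp alternative was fitted on accepted spots, a change made after a fit on all spots gave the same value for every spot. Without the filter on flags, signals below the 1st percentile of accepted spots in a channel, rejected spots included, were set to that percentile. Features without accepted input thus also had a ratio there.

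Scripts were tested on simulated data for 5460 features. With 100 features raised by 1 and 100 by 2 log2 units and spreads drawn from limma's fitted distribution of variances, 48.0% and 100.0% of features enriched over input were recovered, with 9 false calls. Spreads drawn from the observed SDs, the form tried first, which is wider than the spread it stands for, gave 4.00% and 69.0% with 4 false calls; that recovery fell short of the 80% looked for, and the form with fitted variances was added afterwards. For gene lists over 1978 upstream features, a list raised by 2 was called in 20 of 20 runs. Unshifted lists, with the transporter list left out, were called in 0 of 240 tests. Simulated features were independent and did not differ outside the raised list, unlike the data, so these tests say little about false calls here. For intergenic minus ORF, a simulated floor without a class difference gave 0.41 before and -0.01 after matching on input signal, and a simulated difference of 0.5 gave 0.50 after matching. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.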

Results

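Chromatin bound by Tup12 was mapped in the fission yeast Schizosaccharomyces pombe. Tup12 is a corepressor related to budding yeast Tup1; such proteins do not read DNA themselves and are brought to genes by DNA-binding repressors, together with Ssn6. Tup12 carried a GFP tag, cells were taken in mid-log growth in rich medium, and DNA recovered with an antibody against GFP was hybridised beside input DNA on spotted arrays of intergenic regions and open reading frames (ORFs). There were 3 arrays, all of the same kind, described as separate experiments, and no array of an untagged strain was analysed here. Values are log2 ratios of immunoprecipitate over input, so 0 is the median of an array and "enriched" means above that median; errors are SDs over n = 3 arrays. A ratio could be formed for 63.5%, 67.9% and 63.4% of the 19940 genomic spots on replicates 1, 2 and 3, and repeat spots on an array correlated at r = 0.94, 0.93 and 0.94. The labels list input as Cy3 and immunoprecipitate as Cy5 for each array, and the direction of the ratio is taken from them; the protocol words this assignment as the general one. All pairs of arrays correlated positively (r = 0.82, 0.84 and 0.73), so the arrays ran the same way.

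Intergenic features made up most of the enriched features. Of 5460 features with a value on all 3 arrays, 1209 were enriched (22.1%) and 1424 were depleted (26.1%) against the array median at an adjusted p under 0.05 in limma, and 851 were enriched by at least 1 log2 unit and 224 by at least 2. Among intergenic features, 945 of 2238 were enriched (42.2%) and 174 depleted (7.77%). Among ORF features the balance was the other way, with 264 of 3222 enriched (8.19%) and 1250 depleted (38.8%). The median SD of a feature over arrays was 0.41. The balance depends on the zero point: centred on ORF features, 1910 features were enriched and 677 depleted. It also depends on the processing, with 700 and 170 after a second background subtraction, 870 and 53 in the series matrix, and 1066 and 2208 without the filter on flags, where 327 of the enriched features were among the 1209. Without that filter rejected spots were set to a floor value, so features without accepted input also had a ratio. The counts also moved with the arrays used, to 790 and 830 without replicate 1, 1287 and 1354 without replicate 2, and 1016 and 1209 without replicate 3.

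The intergenic features with the highest values lay next to genes of varied function. The region upstream of SPAC1002.20, an uncharacterised gene divergent to psu1 on chromosome I, was highest at 4.46 ± 0.35 (limma adjusted p = 1.7e-11). It was followed by the region between mug24 and hmt1 on chromosome III (4.21 ± 0.39) and the region between rmp1 and the transporter gene SPAC323.07c on chromosome I (4.14 ± 0.31). The shared upstream region of fip1 and fio1, which encode the iron permease and the multicopper oxidase of reductive iron uptake, gave 4.12 ± 0.50 at the fip1 feature and 4.0 ± 0.60 at the fio1 feature. A further feature named for the long intergenic region of fio1 gave 1.30 ± 0.35 (limma adjusted p = 4.0e-04). The region upstream of shu1, a heme uptake gene, gave 4.03 ± 0.43. Upstream of gto1, annotated as an alpha-glucosidase, the value was 4.02 ± 0.36, and at the feature named for ef1-b, a translation factor name that did not match the reference annotation, it was 3.96 ± 0.08. The remaining features of this group were those of pgk1 (3.95 ± 0.22), the vitamin B6 transporter gene SPCC576.17c (3.84 ± 0.71), phf1 (3.81 ± 0.42) and adh1 (3.81 ± 0.17).

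The ORF features with the highest values included 4 reading frames without a gene symbol, each divergent to a named gene. The highest was prt2, at 4.16 ± 0.31, which the array names as a reading frame and the reference annotates as a noncoding RNA gene. SPAPB1A10.13, divergent to alo1, gave 4.12 ± 0.31, mug114, divergent to hxk2, gave 4.05 ± 0.51, and SPBC887.16, divergent to sur2, gave 4.0 ± 0.23. The fip1 ORF itself gave 3.64 ± 0.10. SPAC1F8.08, divergent to the pyruvate decarboxylase gene pdc101, gave 3.53 ± 0.39, and SPAC683.03, divergent to the zinc regulator gene loz1, gave 3.17 ± 0.80. The csc2 ORF stood at 3.23 with an SD of 2.42, so its value rests on arrays that differ widely. At the other end, the features X54421_sanger_27 (-4.03 ± 0.61), cob (-3.70 ± 0.86), cox1 (-3.62 ± 0.22) and X54421_sanger_23 (-3.01 ± 0.50) belong to the mitochondrial genome, and the fifth lowest was the ORF of the nuclear gene atp12 (-2.86 ± 0.47). The 5 mitochondrial features lay 3.38 ± 0.44 below all others on the median, with differences of -2.96, -3.85 and -3.32 on replicates 1, 2 and 3.

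Ranking spots within each array and keeping features whose median rank reached the 85th percentile, the procedure and limit the labels describe, gave a binding list of 739 features. Of these, 607 were intergenic and 132 were ORFs, so that 27.1% of intergenic features and 4.10% of ORF features were in the list (odds ratio 8.71, Fisher's exact test across features, p = 1.3e-134). All but 2 of the list's members were among the enriched features (737 of 739). With features shuffled within arrays, repeat spots kept together, 100 shuffles gave a mean of 327.5 features and at most 366. Without the filter on flags the list held 985 features, of which 222 were among the 739, and the intergenic excess was 4.84 percentage points. In the authors' series matrix the excess was 0.459 percentage points (Fisher's exact test, p = 0.62).

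Intergenic features lay above ORF features on each array. The difference of the medians was 1.01 ± 0.18 log2 units, with 0.94, 1.22 and 0.88 on replicates 1, 2 and 3 (medians 0.53 ± 0.05 and -0.48 ± 0.13). A two-sided exact sign-flip test gave p = 0.25, the smallest that 3 arrays allow. Within bins of equal input signal the difference was 0.47 ± 0.07, and after correction for base composition and length it was 0.16 ± 0.04. Every intergenic feature was given the same 500 bp, so length in that correction nearly names the class. Within bins of equal GC content alone, 0.74 ± 0.12 of an unmatched 1.00 remained. In the authors' series matrix, which holds values of the immunoprecipitate channel alone, the difference was -0.46 ± 0.53. Median signal of accepted immunoprecipitate spots was close for intergenic and ORF features: 1090 and 1148, 1093 and 1021, 1336 and 1346 on replicates 1, 2 and 3. Accepted negative controls gave 911, 968 and 1198. Input medians were lower for intergenic features, at 649 against 1130, 922 against 1888 and 829 against 1446. The typical difference therefore lay mainly in the input.

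Whether regions with more gene starts carried more signal was asked next. Intergenic features were taken to lie upstream of the gene that names them, because of how features correlated with those of neighbouring genes. The correlation was r = 0.67 for divergent neighbours (540 features), against 0.26 for tandem (360 features) and 0.23 for convergent neighbours (432 features). A divergent or convergent pair could enter from each of its genes, so these counts are not of separate pairs. Regions holding gene ends alone were therefore not formed as a class. Divergent upstream regions, which hold the starts of a pair of genes, were in the binding list in 30.6% of 1103 cases, and tandem upstream regions, with a single gene start, in 23.4% of 863 cases (odds ratio 1.45, Fisher's exact test across features, p = 3.6e-04). Features of divergent genes can report the same region, so these features are not independent. The medians differed by 0.07 ± 0.04 log2 units (0.05, 0.06 and 0.11 on replicates 1, 2 and 3; exact sign-flip p = 0.25). This difference ranged from 0.029 without the filter on flags to 0.17 with normexp. Features named for long intergenic regions were lower than other intergenic features by -0.57 ± 0.04, and 15 of 129 were in the list (11.6%, against 28.1%; Fisher's exact test, p = 1.5e-05).

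Iron uptake genes were, with glycolysis genes, the list with the highest upstream signal among the 14 tested. All 10 upstream features in the list, from 8 separate regions, were enriched, also adjusted over the list alone, and all 10 were in the binding list. The long fio1 feature, also enriched and in the binding list, is not among the 10, because features named for long intergenic regions were kept out of the lists. The median of the 10 was 3.35, against 0.53 for other upstream features, a shift of 2.83 ± 0.22 (camera in limma, adjusted p = 1.9e-14 over the 14 lists, and 0.27 with an estimated correlation). With the preset correlation camera rests on the spread across features, and with an estimated one it takes its degrees of freedom from the 3 arrays. Beside fip1, fio1 and shu1, the siderophore transporter gene str3 gave 3.79 ± 0.39, and the lowest of the 10, the siderophore synthesis gene sib2, gave 1.98 ± 0.57. The siderophore transporter gene str1 gave 2.09 ± 0.54 upstream and 0.26 ± 0.48 over its ORF. Over the ORFs of the list, 5 of 9 were enriched, fip1, str3, shu1, fio1 and frp1, and the shift was 1.66 ± 0.27 (camera adjusted p = 1.9e-06 over 15 lists; adjusted p = 0.27 with an estimated correlation).

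Glycolytic and fermentative genes, which are transcribed strongly in glucose medium, had upstream signal of similar height. All 8 measured upstream features were enriched, also adjusted over the list alone, and all 8 were in the binding list, with a median of 3.13 and a shift of 2.60 ± 0.27 (camera adjusted p = 4.3e-10; adjusted p = 0.27 with an estimated correlation). The phosphoglycerate kinase gene pgk1 and the alcohol dehydrogenase gene adh1 led, pdc101 gave 3.44 ± 0.32, and the lowest was the triosephosphate isomerase gene tpi1 at 1.57 ± 0.03. Over their ORFs 5 of 7 were enriched, 6 when adjusted over the list alone, led by gpd3 at 1.75 ± 0.65, with a shift of 1.44 ± 0.23 (camera adjusted p = 1.8e-04; adjusted p = 0.27 with an estimated correlation). Over 14 alternatives tested with camera on upstream features both lists stayed called, with shifts of 2.06 to 4.27 for iron uptake and 1.83 to 4.65 for glycolysis. The order of both lists was not tested and turned with the processing: at equal input signal the upstream shift was 2.77 for glycolysis and 2.44 for iron uptake, after correction for GC content and length 2.92 and 2.84, in the series matrix 4.65 and 4.26, and without features within 200 kb of chromosome ends 2.52 and 2.49.

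Genes repressed by glucose were also enriched upstream, in 10 of 11 cases, and the same count held adjusted over the list alone; 8 were in the binding list. The shift was 1.19 ± 0.09 (camera adjusted p = 9.9e-04; adjusted p = 0.27 with an estimated correlation). Over the 14 alternatives the list stayed called, with shifts from 0.61 without the filter on flags to 3.22 in the series matrix. The call was weakest without features within 200 kb of chromosome ends (shift 0.95, camera adjusted p = 0.032). The highest were gal10 (3.13 ± 0.24) and gal7 (2.91 ± 0.62), neighbouring galactose genes, and mae2 (2.74 ± 0.49), a malic enzyme gene, and the lowest was gut2, a glycerol-3-phosphate dehydrogenase gene, at -0.30 ± 0.34. Over ORFs the shift was 0.82 ± 0.08 with 3 of 12 enriched (camera adjusted p = 4.2e-04; adjusted p = 0.27 with an estimated correlation), led by gal7 at 1.91 ± 0.53. The fructose-1,6-bisphosphatase gene fbp1, a textbook glucose-repressed gene, was represented by a feature named for the long intergenic region upstream (-0.11 ± 0.28) and by its ORF (0.41 ± 0.23), and neither passed the test (limma adjusted p = 0.76 and 0.22).

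Core stress genes were enriched upstream in 11 of 14 cases, the same count when adjusted over the list alone, and all 11 were in the binding list. The shift was 0.86 ± 0.27 (camera adjusted p = 0.0051; adjusted p = 0.27 with an estimated correlation). The calcium-transporting ATPase gene cta3 led with 3.71 ± 0.56 upstream and 1.19 ± 0.36 over its ORF, followed by the heat shock protein gene ssa1 (2.86 ± 0.09) and the peroxiredoxin gene tpx1 (2.57 ± 0.38), and the metallothionein gene zym1 was lowest at -0.42 ± 0.33. Upstream features of membrane transporter genes were enriched in 61 of 101 cases and depleted in 7, with the same counts adjusted over the list alone and 45 in the binding list. The transporter shift was 0.41 ± 0.10 (camera adjusted p = 0.032, and 0.36 with an estimated correlation). The highest transporter feature, that of fio1, also belongs to the iron uptake list, so these lists are not separate evidence. SPAC1B3.15c was lowest at -1.52 ± 0.30. Features whose region holds a tRNA gene were enriched in 14 of 22 cases, 16 when adjusted over the list alone, with a shift of 0.73 ± 0.20 (camera adjusted p = 0.032; adjusted p = 0.32 with an estimated correlation). Over the 14 alternatives the core stress shift ranged from 0.27 to 1.32 (called in 12), that of transporters from 0.091 to 0.93 (called in 8) and that of tRNA regions from 0.25 to 1.13 (called in 9). The transporter call was lost without replicate 3 (camera adjusted p = 0.053), without features near chromosome ends (0.19), with features of long intergenic regions included (0.16), with either further background or control subtraction (0.085 and 0.099) and without the filter on flags (0.89). The core stress call was lost with further background subtraction (0.11) and without the filter (0.12). The tRNA call was lost without replicate 3 (0.060), with loess (0.054), with dim input left out (0.43), after correction for GC content and length (0.48) and without the filter (0.16). The tRNA shift was 0.43 at equal input signal.

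The other lists were not called against other upstream features, although some were under single alternatives. All 8 upstream histone features, from 5 regions, were enriched against the array median, led by hht2 at 1.58 ± 0.47, yet the shift of 0.84 ± 0.04 did not pass camera (adjusted p = 0.13). It did in 5 of 14 alternatives, with shifts of 0.30 to 1.91 over the 14. Over ORFs the list passed (1.10 ± 0.13, adjusted p = 0.015; adjusted p = 0.36 with an estimated correlation), with 4 of 8 enriched and 2 depleted. Of phosphate, zinc and copper genes, 5 of 7 were enriched, the phosphate transporter gene pho84 most (3.31 ± 0.77), with a shift of 0.80 ± 0.28 (adjusted p = 0.13). That shift was -0.048 without features within 200 kb of chromosome ends (adjusted p = 0.95) and 2.62 in the series matrix. Of mating and meiosis genes, 3 of 7 were enriched, the meiotic inducer mei3 at 3.53 ± 0.10, map2 at 2.84 ± 0.34 and mei2 at 1.38 ± 0.48 (list shift 0.04 ± 0.59, adjusted p = 0.17). Of nitrogen starvation genes, 5 of 7 were enriched, led by isp5 at 2.57 ± 0.53 (shift 0.73 ± 0.39, adjusted p = 0.19; 0.24 without chromosome ends and 1.97 in the series matrix). Of corepressor and regulator genes, 4 of 10 were enriched, prr1 (2.77 ± 0.53), sty1 (2.07 ± 0.44), toe1 (1.59 ± 0.25) and pap1, with a list shift of 0.04 ± 0.31 (adjusted p = 0.36). Ribosomal protein genes went both ways, with 31 of 73 enriched and 6 depleted, from rpl2301 at 2.84 ± 0.15 to rpl2802 at -1.10 ± 0.34, and a shift of -0.20, -0.13 and -0.03 on replicates 1, 2 and 3 (-0.12 ± 0.09; -0.0085 on the means of features, camera adjusted p = 0.45). For wtf genes 5 of 11 were enriched (shift 0.07 ± 0.21, adjusted p = 0.59) and for cell-surface adhesins 3 of 5 (shift 0.18 ± 0.13, adjusted p = 0.86). At equal input signal, where a shift is closer to a mean over members than to a median, it was 0.81 ± 0.12 for regulators, 0.74 ± 0.20 for mating and meiosis and 0.78 ± 0.14 for wtf. The unmatched means were 0.42 ± 0.07, 0.69 ± 0.27 and 0.26 ± 0.14, and these values were not tested. The wtf and Tf2 families have near-identical copies, so their values are uncertain. Upstream, Tf2 retrotransposons and translation factors had 1 measured feature each, Tf2-1 at 1.09 ± 0.19 and tif51 at 1.06 ± 0.24, and were not tested as lists.

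**Figure D1:**
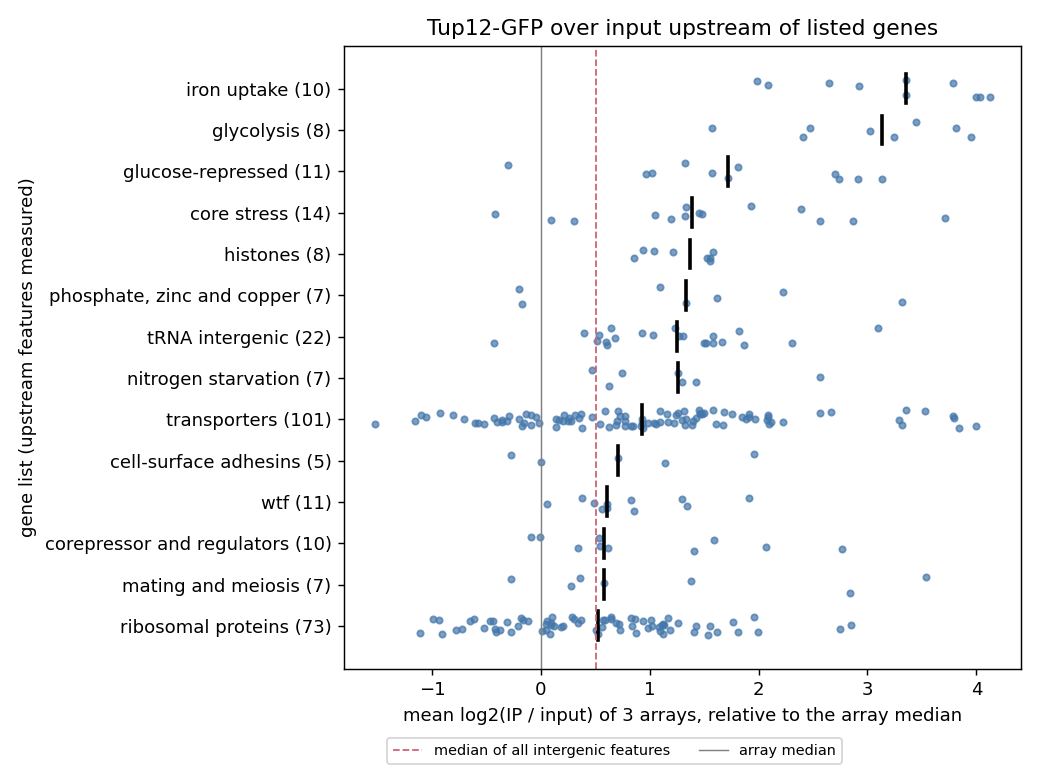
Mean log2 ratio of immunoprecipitate over input (horizontal axis, mean of 3 arrays, relative to the array median) of each upstream feature in the 14 gene lists tested (rows, with the number of features measured). Each point is a feature, black bars are list medians, the dashed line is the median of all intergenic features and the grey line is the array median. Features named for long intergenic regions are not plotted. The plotted iron uptake features lie at 1.98 or above and the ribosomal protein median, 0.52, lies at the dashed line.

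Of the corepressor's own genes, the measured features of ssn6 and the tup11 ORF were not enriched. The ssn6 upstream feature gave 0.54 ± 0.41 (limma adjusted p = 0.12) and the ssn6 ORF -0.88 ± 0.27 (limma adjusted p = 0.010). The ORF of tup11, the paralogue of tup12, gave -1.47 ± 0.24 (limma adjusted p = 9.3e-05), while the input of its upstream feature was accepted on 1 of 6 spots, so the only ratio was 1.74, on replicate 2. The ORF of ste11, a regulator of sexual differentiation, gave 0.18 ± 0.40, and no feature name matched tup12.

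Toward the ends of chromosomes I and II, signal was high in a belt set back from the end. Features within 100 kb of an end lay 0.69 ± 0.03 above features elsewhere on the median (0.65, 0.71 and 0.69 on replicates 1, 2 and 3; exact sign-flip p = 0.25), and 43 of 134 were in the binding list (32.1%, against 12.7%; Fisher's exact test across features, p = 1.2e-08). The size of this excess depends on the processing, with 0.25 without the filter on flags, 1.10 with normexp, 1.07 with a second background subtraction and 1.86 in the series matrix. It was 0.46 ± 0.09 for intergenic and 0.75 ± 0.02 for ORF features. By distance, chosen after the values were seen, the outermost 50 kb had a median of 0.01 ± 0.07 with 6 of 70 features in the list. The next 50 kb had a median of 1.32 ± 0.11 with 37 of 64. The stretches from 100 to 150 kb and from 150 to 200 kb had medians of 0.45 ± 0.11 and -0.05 ± 0.08. Split by kind, intergenic features stayed high beyond the 50 to 100 kb belt, where their median was 1.65 ± 0.17. From 100 to 150 kb it was 1.40 ± 0.10 for 39 intergenic features, and from 150 to 200 kb 0.49 ± 0.11. ORF medians over these 3 stretches were 1.10 ± 0.04, 0.05 ± 0.13 and -0.45 ± 0.18, so the belt ended earlier for ORFs. Genes in the high belt included shu1, str3, gal10, gal7, pho84, the glucose transporter family gene ght3 (1.72 ± 0.26 upstream) and the acid phosphatase gene pho1 (1.62 ± 0.32 upstream). By arm, the median there was 1.77 for 22 features on the left and 0.59 for 19 on the right of chromosome I, and 0.82 for 7 on the left and 1.52 for 16 on the right of chromosome II. Features within 50 kb of the centromeres, placed at the longest stretch without protein-coding genes, did not differ from elsewhere beyond the spread of the arrays (0.02 ± 0.10; 14 of 138 in the list, Fisher's exact test, p = 0.44). They lay lower beyond that spread without the filter on flags (-0.10 ± 0.04), after a second background subtraction (-0.10 ± 0.07) and in the series matrix (-0.07 ± 0.01). By kind, the centromere difference in the main values was -0.16 ± 0.16 for intergenic features, below 0 on each array, and 0.12 ± 0.20 for ORF features. Distances come from gene positions in the ASM294v3 annotation, matched by gene name.

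**Figure D2:**
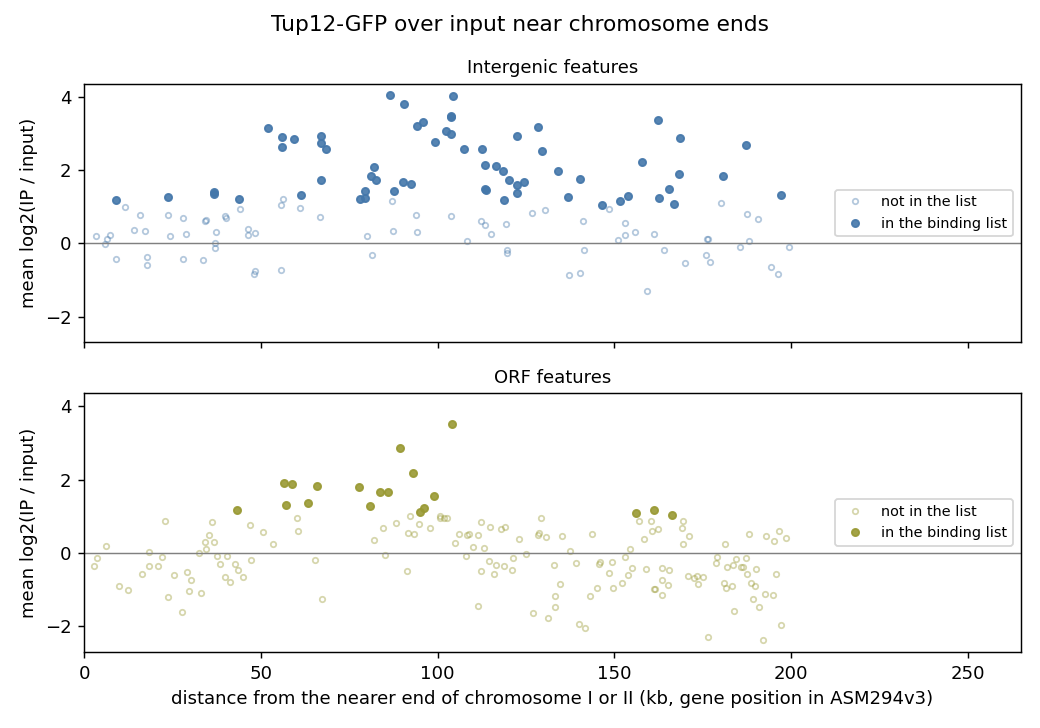
Mean log2 ratio of immunoprecipitate over input (vertical axes, mean of 3 arrays, relative to the array median) of intergenic features (top) and ORF features (bottom) against distance from the nearer end of chromosome I or II in kb. Filled points are in the binding list; between 50 and 100 kb from an end 37 of 64 features are filled, and in the outermost 50 kb 6 of 70.

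The 3 arrays ranked features alike. Across the 5460 features, Pearson's r was 0.82 between replicates 1 and 2, 0.84 between 1 and 3 and 0.73 between 2 and 3 (Spearman's rho 0.79, 0.81 and 0.68); features are not independent replicates. Of the 819 highest features of each array, 593, 581 and 507 were shared by these pairs and 467 by all 3 arrays, against 18.4 for independent rankings. On each array the ratio fell with input signal (r = -0.56, -0.62 and -0.55 across features), so dim features tend to higher ratios. Input is the denominator of the ratio, so part of this fall is built in.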

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

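The tests within bins of equal input signal and without features near chromosome ends were chosen after the data were seen, as were the signals given first.

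Signals outside the comparisons stood out at features of foreign DNA. The GFP coding feature had a mean input signal of 8953 (SD 1124 over arrays) and the KanMX marker feature one of 2688 (SD 525), while Luciferase averaged 3.31 and LacZ, Gst, Gal4 and LexA features and the TAP tag feature were at 0 in the input. Of 1493 features without accepted input on any array, 9 had immunoprecipitate signal above the 95th percentile of negative control spots on all 3 arrays. They were the ORFs of gls1, hit1, rpm1 and SPAC30.11 and the upstream features of lys1, mug191, npp106, sec18 and a tRNA isoleucine gene, with gls1 highest at 2.13 ± 1.37 times that percentile. A strain with GFP-tagged Tup12 carries GFP coding DNA, so its input holds DNA for the GFP feature. No explanation was tested for the other signals.

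Intergenic features lay above ORF features, and with a single group no biological explanation was tested. Base composition alone is argued against as the whole cause, since within bins of equal GC content the difference was 0.74 ± 0.12 of an unmatched 1.00 (0.72 to 0.77 of it on single arrays), over the 66.1% of features in shared bins, with intergenic GC content taken from a 500 bp window. The planned joint correction for GC content and length left 0.16, but every intergenic feature was given the same 500 bp, so that length there nearly names the class. Signal left in the immunoprecipitate channel of dim spots may account for part of the excess, because within bins of equal input signal 0.47 ± 0.07 remained, 0.44 to 0.52 of the unmatched difference on single arrays. Intergenic features are also the dimmer ones, so dim-spot signal and binding cannot be told apart for the part that was lost.

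Glycolysis genes had high upstream signal, and no biological explanation was tested for it. Dim spots are argued against, as the shift against upstream features of equal input signal was 2.77 ± 0.13, compared with 2.60 unmatched by medians and 2.44 by the mean of members. Another explanation is signal at highly transcribed genes whatever protein is precipitated. The glycolysis list was itself fixed beforehand as a list where such signal would be looked for. So were ribosomal proteins, translation factors, histones and tRNA regions. The ribosomal protein list, with a shift of -0.12 ± 0.09 on the mean of arrays, argues only against such signal at all highly transcribed genes alike. The feature named for ef1-b (3.96 ± 0.08), the 8 enriched upstream histone features and the tRNA regions (shift 0.73 ± 0.20, camera adjusted p = 0.032) go the other way. Such signal could therefore still contribute at some regions, and whether it does at glycolysis genes cannot be decided from these lists. Unspecific recovery by the GFP antibody stays open, since an untagged strain was not analysed here.

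Iron uptake genes had high upstream signal too, and no biological explanation was tested for it either. Against upstream features of equal input signal their shift was 2.44 ± 0.13, compared with 2.72 unmatched by medians and 2.68 by the mean of members, which argues against dim spots as the whole cause. The ribosomal protein list's shift of -0.12 argues here too only against signal at all highly transcribed genes alike. The ef1-b, histone and tRNA features again go the other way. The iron uptake shift was 2.49 with features within 200 kb of chromosome ends left out. Unspecific recovery by the antibody stays open for them as for glycolysis genes.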

How the results depend on the processing

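The alternatives with control-level subtraction, equal input signal, 2 arrays, single features per region, left-out list members, left-out chromosome ends and included long intergenic regions were chosen after the data were seen, as was fitting normexp on accepted spots alone. The upstream shifts of iron uptake and glycolysis stayed positive and past the threshold in 14 alternatives tested with camera on upstream features (iron uptake 2.06 to 4.27, highest adjusted p = 0.0020; glycolysis 1.83 to 4.65, highest adjusted p = 0.0018, in limma), with the estimated correlation as the exception. Of the named features' values under alternatives, 2021 were counted as the same, 126 lost the call, 46 gained one and 17 were counted as changed in sign. A change of sign where neither value passed the threshold was not counted. The loz1 ORF, at 0.26, -0.11 and -0.11 on replicates 1, 2 and 3, is a case, as it turns without replicate 1. Signal over background limits which spots have a ratio. Without the filter on flags, where rejected spots were set to a floor value, 327 of 1066 enriched features were among the 1209. Unless stated, the cause was not tested.

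Without single replicates, enriched features ranged from 790 to 1287 and depleted from 830 to 1354, the lowest both without replicate 1; agreement r ranged from 0.73 to 0.84, the transporter shift from 0.35 to 0.42 and the tRNA shift from 0.60 to 0.85, both lists losing their calls without replicate 3.

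With loess, 910 features were depleted, the divergent minus tandem difference was 0.11, the phosphate, zinc and copper list gained a call (1.11) and tRNA regions lost theirs (0.55). With normexp the intergenic minus ORF difference was 1.44, divergent minus tandem 0.17, the chromosome end excess 1.10, and histones gained a call (1.08). With background subtracted a second time, 700 features were enriched and 170 depleted, these differences were 1.31, 0.12 and 1.07, the centromere difference -0.10 and agreement 0.68. Core stress (1.20) and transporters (0.93) lost their calls, and wtf11 upstream (-0.030) and rps21 (-0.94) changed sign.

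Without the filter on flags, 2208 features were depleted, divergent minus tandem was 0.029, chromosome ends 0.25, centromeres -0.10 and agreement 0.67. There, 3 lists were called, with core stress (0.27), transporters (0.091) and tRNA regions (0.25) lost, and htb1 (-0.029) and SPAC2E1P3.02c (-0.016) changed sign. With the lowest 20% of input left out, 907 features were depleted, intergenic minus ORF was 0.77, divergent minus tandem 0.15 and chromosome ends 0.63. Histones gained a call (1.38) and tRNA regions lost theirs (0.44).

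The series matrix differs in several choices at once (a single channel, a further background subtraction, block constants and a floor), so no difference can be put down to any of them. There, 53 features were depleted, intergenic minus ORF was -0.46 and 0.459 percentage points in the list, divergent minus tandem 0.16, chromosome ends 1.86 and agreement 0.64; 11 lists were called, with regulators (2.41), histones (1.91), nitrogen starvation (1.97), phosphate, zinc and copper (2.62) and wtf (2.36) gained. The ORF features of cox1 (0.11), SPAC977.07c (3.39), hta2 (0.91), rpl14 (-0.45), rps21 (-1.43), tf2-6 (3.04), eft2 (2.06), wtf8 (3.41) and wtf11 (1.46) changed sign, as did upstream features of SPBC21D10.06c (-0.14), gut2 (2.19), SPBC1271.09 (1.70) and SPAC1B3.15c (1.23).

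Centred on ORF features, 1910 features were enriched and 677 depleted. At the 90th percentile the list held 478 features, and with both kinds ranked separately the intergenic excess was 1.20 percentage points, by construction. Correction for GC content and length, where length nearly names the class, left an intergenic minus ORF difference of 0.16. Under that correction histones gained a call (1.07) and tRNA regions lost theirs (0.43). With an estimated correlation 0 lists were called by camera: iron uptake (2.83), glycolysis (2.60), glucose-repressed (1.19), core stress (0.86), transporters (0.41) and tRNA regions (0.73) kept their shifts, which do not depend on it. With fry, which asks whether a list lies off the array median, 14 were called, adding adhesins (0.18), regulators (0.045), histones (0.84), mating (0.043), nitrogen starvation (0.73), phosphate, zinc and copper (0.80), wtf (0.074) and ribosomal proteins (-0.0085, called upward by fry). Over ORFs, core stress (0.13) and transporters (0.0060) lost their calls and histones gained one (1.10); with the higher of both features histones were called (1.20).

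At 50 kb and 200 kb the chromosome end excess was 0.13 and 0.49, and without members of the fixed lists 0.61. With the control level subtracted, divergent minus tandem was 0.11, chromosome ends 0.92, histones gained a call (1.14) and transporters lost theirs (0.39); without chromosome ends (0.27) and with long intergenic regions included (0.24) transporters lost theirs too. At equal input signal, intergenic minus ORF was 0.47 and divergent minus tandem 0.13, and shifts were 0.43 for adhesins, 1.18 for core stress, 0.81 for regulators, 1.41 for glucose-repressed, 1.00 for histones, 2.44 for iron uptake, 0.74 for mating, 0.43 for tRNA regions and 0.78 for wtf.

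No paired analysis was possible because the series holds a single group.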

Other observations

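The comparisons by upstream gap and by the state of a gene's own upstream region were chosen after the data were seen; the test of ORF length was written down before it was run.

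Upstream features of genes with longer upstream gaps had higher ratios, leaving aside features named for long intergenic regions, which were lower than other intergenic features (by -0.57 ± 0.04). In 4 groups of near-equal size by distance from the start codon to the next gene, the median log2 ratio of upstream features was 0.14, 0.52, 0.72 and 0.72 from shortest to longest, and 11.6%, 24.8%, 35.3% and 38.2% of features were in the binding list (Spearman's rho 0.25 across features, which are not independent). The group with the shortest gaps reached up to 496 bp, and that with the longest began at 1540 bp. The median log2 input signal was 9.83, 9.66, 9.59 and 10.002 in these groups, and the longest minus the shortest differed by 0.62 ± 0.03, or by 0.71 ± 0.09 within bins of equal input signal.

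ORFs were in the binding list mostly where their own upstream feature was. Among 379 ORFs with an upstream feature in the list, 77 were themselves in it (20.3%), against 16 of 912 ORFs whose upstream feature was not (1.75%; odds ratio 14.2, Fisher's exact test across features, p = 1.1e-28), and the medians differed by 0.66 ± 0.12. One hypothesis is that chromatin fragments reaching from a bound upstream region into the ORF may give this signal, in which case short ORFs would be higher. Where the upstream feature was in the list, Spearman's rho of the ORF value with length from start to stop codon was -0.35 ± 0.03 over arrays, against -0.07 among the other ORFs. In 4 groups of near-equal size from the shortest ORFs (156 to 699 bp) to the longest (1743 to 7366 bp), 41.1%, 16.8%, 17.0% and 6.32% were in the list. This is what the hypothesis needs, and Tup12 that itself spreads a short way into genes would give the same trend.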
